A study of Caenorhabditis elegans with 2 samples.

How the data were processed

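LIN-35 tagged with GFP and FLAG was immunoprecipitated from whole, mixed-sex young adult worms of strain YL402, and the DNA was sequenced, as the labels describe. The labels give biological replicate numbers 2 and 3 for the libraries, each with technical replicate number 1 and a size range of 150 to 350. Both libraries belong to 1 group, and a control alignment was used in calling, per the text deposited with the samples. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Per that deposited text, candidate regions were called in each replicate and in the pooled alignments, and the thresholded list was derived from the pooled list and both replicate lists.

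Each deposited list gives regions with a summit and a signal value, which is the authors' enrichment signal for that region. Its scale is not given in the sources used here, and it was used only to rank and describe regions within a list. The deposited lists also give −log10 q-values by their column order, and all 396 thresholded peaks carry the same value, 3.22. Lists were deposited on builds ce10 and ce11. All results are from ce11 (equal to WBcel235) except the counts named as ce10, and no coordinates were converted. The thresholded list held 396 peaks on ce11, 394 after merging overlapping ones, and 408 on ce10. Coordinates are 1-based.

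Each of the 396 thresholded peaks was identical to a pooled candidate region. Gene starts, exons and UTRs were taken from the Ensembl release 115 annotation with 19985 protein-coding genes, and sequence from the matching reference. All region ends fitted the reference chromosome lengths. The background for peak properties was the 29591 pooled candidate regions that overlapped no thresholded peak. For motifs, candidate regions were drawn with a fixed seed in the same proportions within and beyond 500 bp of a gene start, 10 per peak. For intergenic, exon and intron classes a single annotation order was used (UTR, coding exon, intron, intergenic). Shares were compared by two-sided Fisher's exact tests, with exact Clopper-Pearson 95% intervals. These treat peaks and genes as independent, and they measure counting error, not the spread between worm populations. For replicate overlap, the 396 highest-ranked regions of each library were compared, with 1000 random draws of 396 regions from each list as the reference.

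The 16 gene lists (DNA replication, cell cycle and mitosis, meiosis, germ granule and small RNA, germline RNA-binding, DNA repair, DREAM and synMuv B, proteasome, ribosomal protein, histone, mitochondrial respiratory chain, cuticle collagen, vitellogenin and intestine, muscle structure, neuron, major sperm protein) were fixed before the data were examined, as were the motifs and the main distances. A total of 2 list names did not match the annotation. Lists were tested among the 6873 genes with a candidate region within 500 bp, with Benjamini-Hochberg adjustment over the lists. Genes were named by a fixed rule: the nearest gene of the 12 peaks with the highest signal, up to 4 bound members of each list with the highest signal, the 3 transgene parts, and 8 DREAM genes whether bound or not. Further members were named where a list was given in full, and other exceptions are stated in the text.

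On simulated data, the list test recovered the cell cycle and mitosis list in 94.5% of 200 simulations with a 6-fold higher chance of binding, in 40.0% with a 3-fold higher chance and in 0.5% with none, over 6873 genes. Overlaps were checked against bedtools, the motif search on sequences with planted motifs, and the 6-mer scan on 150 random windows with a planted 6-mer, which was called with 1 other among 2080. Depth per library was not used here, so no interval reflects read numbers.

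Tests of shared promoters, of summits upstream of starts, of tRNA genes near X peaks, of replicate ranks by signal and of motif shares by signal were added after the data were seen. Alternatives covered the distance (250 and 1000 bp), a stricter set of the 198 peaks with the highest signal, each replicate list alone, removal of peaks near small RNA genes, other motif definitions and windows, other backgrounds, the nearest gene only, other overlap definitions and the ce10 lists. Alternatives added after seeing the data were nuclear peaks only, the 1000 or 2000 highest-ranked pooled regions, removal of the 8 peaks at transgene parts (gene and 3000 bp on each side), a background matched on GC content within 2 percentage points, and the starts of other genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.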

Results

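LIN-35 is the only retinoblastoma-like pocket protein of *Caenorhabditis elegans* and part of the DREAM complex, which also holds the E2F-DP pair EFL-1 and DPL-1 and the DNA-binding subunit LIN-54. Binding of LIN-35 was mapped by ChIP-seq in whole young adult worms of a strain carrying an integrated transgene, in which the germline-expressed *pie-1* promoter drives LIN-35 fused to GFP and FLAG tags and an *unc-119* copy rescues the mutant background. The 2 libraries, biological replicates 2 and 3, form a single group, so the measurements describe where binding was found and no comparison between conditions was possible. The lists held 20291 candidate regions in replicate 2, 30000 in replicate 3 and 30000 after pooling, of which 396 peaks passed the authors' irreproducible discovery rate (IDR) threshold. The 396 peaks were the 396 pooled regions with the highest deposited signal, which ran from 29.96 to 706.6 with a median of 44.8. Read numbers were not used here, so the depth behind each peak is unknown, and the intervals below cover only the number of peaks or genes counted.

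Replicate agreement was examined first, because ranks in the 2 libraries are the only measure of spread in this design. The strongest nuclear peaks ranked high in both libraries. The peak upstream of the ribosomal protein gene *rpl-3* ranked 4 in replicate 2 and 9 in replicate 3, and the peak upstream of *cdc-48.1*, which encodes a p97 segregase, ranked 10 and 5. Of the 396 highest-ranked regions of replicate 2, 192 (48.5%, exact Clopper-Pearson 95% interval 43.5% to 53.5%) overlapped by at least 1 bp a region among the 396 highest-ranked of replicate 3. Drawing 396 regions at random from each list gave a mean overlap of 1.32 and at most 7 in 1000 draws (one-sided permutation p = 0.001, the smallest that these draws can give). The thresholded list was derived from both replicate lists and their pool, so its overlap with them was not taken as a measure of agreement. Not all of its peaks were found in both, as 357 of the 376 nuclear peaks overlapped a candidate region in both lists. Among nuclear peaks with a region in both lists, ranks were more than 10-fold apart at 6 of the 89 peaks with the highest signal (6.74%) and at 23 of the 89 with the lowest (25.8%; Fisher's exact p = 9.1e-04, a test chosen after the ranks were seen). Such gaps also occurred at stronger peaks. The *mex-1* peak (pooled rank 63) had rank 34 in replicate 2 and 1340 in replicate 3, and *rpl-5* (pooled rank 94) had 54 and 1589. At the weaker *psf-3* peak (pooled rank 259), near the gene for a subunit of the replicative GINS complex, the ranks were 147 and 3694.

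**Figure D1:**
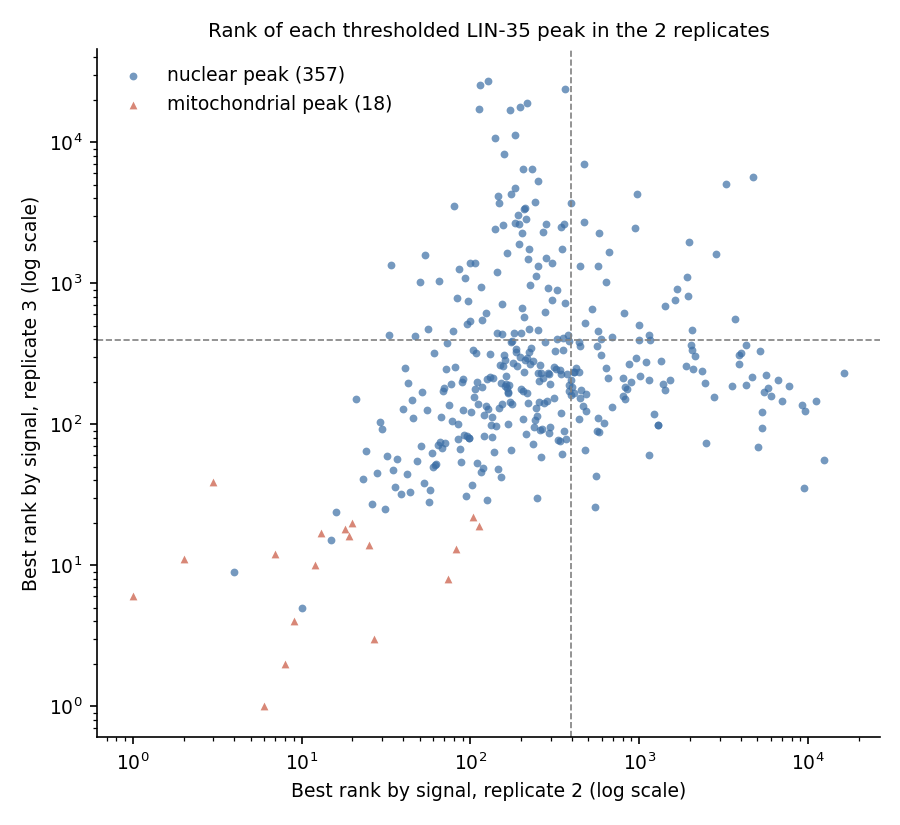
Best rank by deposited signal of each thresholded peak in replicate 2 (x axis) and replicate 3 (y axis), both on log scales, for the 357 nuclear and 18 mitochondrial peaks that overlapped a candidate region in both libraries. Dashed lines mark rank 396, and the 18 mitochondrial peaks lie at the high-ranked end in both libraries.

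LIN-35 peaks lay mainly in intergenic sequence just upstream of genes. Of the 396 summits, 330 (83.3%, 95% interval 79.3% to 86.9%) were within 500 bp of the start of a protein-coding gene, compared with 6603 of 29591 candidate regions that overlapped no peak (22.3%; two-sided Fisher's exact test, p = 2.9e-144). The median distance of nuclear summits to the nearest start was 203 bp, with quartiles of 108 and 312 bp. Of the 316 nuclear summits within 500 bp of a start, 293 (92.7%) were upstream of it, compared with 52.7% of candidate regions within the same distance (Fisher's exact p = 9.0e-53). Starts on both strands lay within 500 bp of 94 of these 316 summits (29.7%), compared with 7.76% of candidate regions (Fisher's exact p = 1.7e-28). These shared promoters included those of *orc-5* and *cyb-1*, of *rec-8* and *mex-5*, and of *rpl-12* and *lin-54*. Intergenic summits numbered 322 (81.3%), and 27 lay in introns, 25 in coding exons, 19 in 5′ UTRs and 3 in 3′ UTRs.

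The X chromosome held few LIN-35 peaks, in a strain where the germline-expressed *pie-1* promoter drives the tagged protein. Whether this holds in somatic tissue cannot be told from these data. Only 9 of the 396 peaks (2.27%, 95% interval 1.04% to 4.27%) were on X, compared with 5984 of 29591 candidate regions (20.2%; Fisher's exact p = 1.1e-26). Peak density was 0.508 per Mb on X, and on the autosomes it ranged from 2.96 per Mb on chromosome V to 6.02 per Mb on chromosome III. The strongest X peak ranked 252, and 5 of the 9 lay within 500 bp of a tRNA gene, compared with 1 of 367 autosomal peaks (Fisher's exact p = 1.2e-08). Candidate regions near tRNA genes were also more frequent on X, 168 of 5984 (2.81%) compared with 181 of 23605 on autosomes (0.77%; Fisher's exact p = 8.4e-32). The mitochondrial genome held 20 peaks, which is 5.05% of the set, with a median signal of 180.9. The X share was 5.30% with the 396 highest-ranked regions of replicate 3 alone and 1.09% without peaks near tRNA, rRNA, snoRNA and snRNA genes, both below that of candidate regions.

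The DREAM complex can contact DNA through the E2F-DP pair and through LIN-54, which recognises the cell cycle genes homology region (CHR). An E2F motif (TTSSCGC, where S is C or G) was present within 100 bp of 197 of the 396 summits (49.7%, 95% interval 44.7% to 54.8%), compared with 336 of 3960 candidate regions at similar distances from gene starts (8.48%; Fisher's exact p = 3.0e-86). A CHR motif (TTYGAA, where Y is C or T) was present at 284 summits (71.7%, 95% interval 67.0% to 76.1%), compared with 52.6% of those candidate regions (Fisher's exact p = 1.7e-13). Both motifs were concentrated at nuclear summits. The E2F motif began in the 50 bp to the left of the summit in 24.2% of nuclear peaks and in the 50 bp to the right in 25.8%, compared with 2.13% in the outermost 50 bp of the 500 bp to the left. For the CHR motif the corresponding shares were 29.0%, 25% and 17%. The E2F motif was found in 63 of the 94 nuclear peaks with the highest signal (67.0%) and in 38 of the 94 with the lowest (40.4%; Fisher's exact p = 4.2e-04). The CHR shares of the same peaks, 80.9% and 70.2%, differed in the same direction (Fisher's exact p = 0.13). Whether the motifs differ in this respect was not tested. The E2F share fell to 31.7% when the 1000 highest-ranked pooled regions were used, against 7.30% in the remaining candidate regions.

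**Figure D2:**
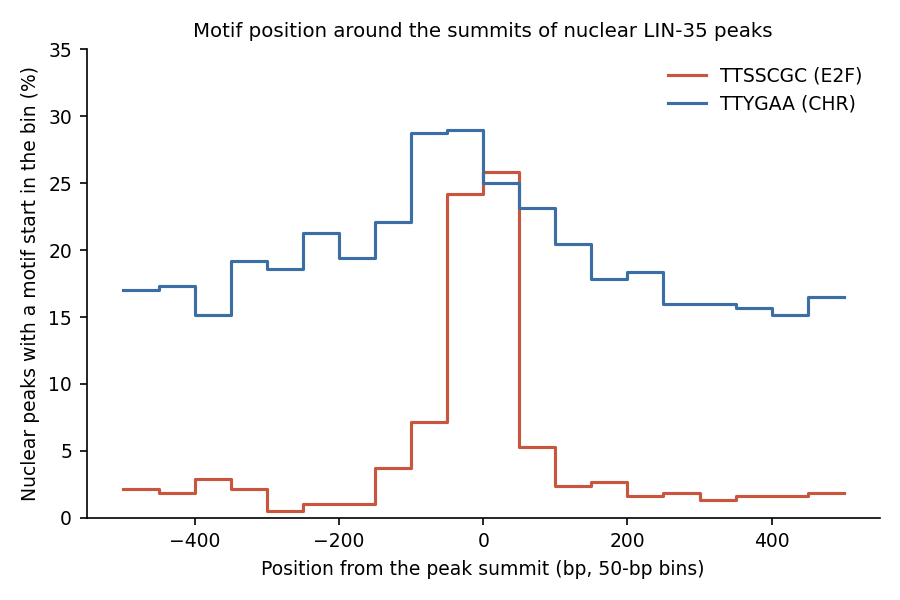
Share of the 376 nuclear peaks (y axis, percent) in which an E2F motif (red) or a CHR motif (blue) began in each 50-bp bin around the summit (x axis, bp; left is towards lower chromosome coordinates). The E2F share reached 25.8% beside the summit and lay between 0.53% and 3.72% in bins more than 100 bp away, and the CHR share reached 29.0%.

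Of the 12 peaks with the highest signal, 9 were on the mitochondrial genome. Their nearest protein-coding starts were those of ND1, a subunit of respiratory complex I, and of the genes WBGene00000829, WBGene00010958, WBGene00010960, WBGene00010961, WBGene00010965, WBGene00010966 and, for a pair of peaks, WBGene00010967. The other 3 were nuclear. The *rpl-3* peak spanned 3867451 to 3867678 on chromosome III (ce11), had a signal of 278.8 and its summit 276 bp upstream of the gene start, in intergenic sequence. The *cdc-48.1* peak spanned 10563466 to 10563686 on chromosome II, with a signal of 254.5 and its summit 178 bp upstream of the start. The *rpl-35* peak spanned 7854578 to 7854790 on chromosome III, with a signal of 190.9 and its summit 457 bp upstream. The next nuclear peaks, chosen after their values were seen, lay at *tasp-1* (a threonine aspartase, signal 165), *sec-61.G* (a subunit of the Sec61 protein channel, 129.1), *knl-3* (a kinetochore protein, 126.9) and *ddp-1* (a mitochondrial import factor, 125.2). An E2F motif was present at the *cdc-48.1*, *tasp-1*, *sec-61.G* and *knl-3* summits and not at *rpl-3*, *rpl-35* or *ddp-1*.

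A protein-coding gene was called bound when a peak summit lay within 500 bp of its start. There were 420 bound genes, 408 of them nuclear, among 6873 genes with a candidate region within the same distance. Genes of DNA replication and of mitosis were bound more often than other genes. In the DNA replication list, 12 of 30 genes with a candidate region were bound (40.0%, 95% interval 22.7% to 59.4%), compared with 5.96% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted p over the 16 lists = 5.9e-07), and 26.7% with the 396 highest-ranked regions of replicate 3 alone. The strongest peaks were at *pcn-1*, encoding the sliding clamp PCNA (signal 95.8), *mcm-2*, a subunit of the replicative helicase (89.3), *top-2*, encoding topoisomerase II (88.7), and *rfc-4*, a clamp loader subunit (55.2). Other bound members were *mcm-3*, *mcm-7*, *pri-2*, *pola-1*, *psf-3*, *dut-1*, *orc-1* and *orc-5*. The *dut-1* and *orc-1* peaks overlapped no candidate region of replicate 3. Several peaks of this list are shared with another gene, among them that of *top-2* with *npp-3* and that of *rfc-4* with *eef-1A.1*. The cell cycle and mitosis list had 14 of 40 genes bound (35%, 95% interval 20.6% to 51.7%; others 5.94%; adjusted exact p = 5.9e-07), and 8 of 37 (21.6%) with replicate 3 alone. Its strongest peaks were at *knl-3* (126.9), *csc-1*, a member of the chromosomal passenger complex (73.7), *klp-18*, a kinesin of the meiotic spindle (62.8), and *sas-5*, a centriole assembly factor (62.8). Several of these are shared too, among them the *csc-1* peak with *fbxc-23* and the *klp-18* peak with *cogc-2*. The E2F motif was present at 11 of the 12 replication peaks and at 11 of the 14 cell cycle peaks.

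Genes encoding germline RNA-binding proteins were bound at 9 of 19 (47.4%, 95% interval 24.4% to 71.1%; others 6.0%; adjusted exact p = 2.9e-06), and at 31.6% with replicate 3 alone. *mex-5*, a determinant of embryonic polarity, had a signal of 85.6 at a promoter shared with the meiotic cohesin gene *rec-8*. *mex-1* had 80.3, *pie-1* 59.5 and *oma-1*, a regulator of oocyte maturation, 55.6. The other 5 were *puf-3*, *puf-5*, *puf-11*, *spn-4* and *daz-1*. The *daz-1* peak overlapped no candidate region of replicate 3. The *pie-1* promoter is also part of the transgene, and without the peaks at transgene parts 8 of 19 genes were bound. The other germline lists did not pass the test. Meiosis genes were bound at 4 of 18 (22.2%; adjusted exact p = 0.057), at *rec-8*, *zhp-2*, *coh-4* and *pch-2*. Germ granule and small RNA genes were bound at 1 of 24 (4.17%; adjusted exact p = 1), at *glh-2*, and at 3 of 20 (15%; others 6.97%; adjusted exact p = 0.37) with the 396 highest-ranked regions of replicate 2 alone.

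Genes of the DREAM complex and the related synMuv B group were bound at 7 of 14 (50%, 95% interval 23.0% to 77.0%; others 6.02%; adjusted exact p = 2.3e-05), at 6 of 14 (42.9%) without the peaks at transgene parts, which include *lin-35*, and at 35.7% with replicate 2 alone. Peaks lay at 5 of the 8 DREAM genes examined. The *lin-9* peak (chromosome III, 88 bp from the start) had a signal of 89.1, *lin-53* (chromosome I, 257 bp) 83.6, *efl-1* (chromosome V, 171 bp) 74.4, *lin-54* (chromosome IV, 325 bp) 64.3 and *lin-35* itself (chromosome I, 147 bp) 42.2. The remaining bound members were the heterochromatin protein gene *hpl-2* and *lin-61*. The *hpl-2* peak overlapped no candidate region of replicate 2. No thresholded peak lay within 500 bp of the starts of *dpl-1*, *lin-37* or *lin-52*. The *lin-53* peak is shared with *nra-2*, the *lin-54* peak with *rpl-12*, the *lin-35* peak with *vps-51* and the *lin-61* peak with *bub-1*. These shared peaks cannot be assigned to a single gene. With the nearest gene only, 4 of 11 genes of this list were bound (36.4%; others 5.1%; adjusted exact p = 0.0055).

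Ribosomal protein genes formed the list with the most bound members, 16 of 63 (25.4%, 95% interval 15.3% to 37.9%; others 5.93%; adjusted exact p = 2.9e-06). After *rpl-3* and *rpl-35*, the strongest were *rpl-24.2* (75.5) and *rpl-5* (67.0), the latter at a promoter shared with the collagen gene *col-38*. An E2F motif was present at 4 of the 16 ribosomal protein peaks, compared with 21 of the 25 peaks at replication and cell cycle genes (Fisher's exact p = 2.6e-04, a test chosen after the values were seen). These 4 peaks lay at promoters shared with another gene. Of the other lists with at least 4 peaks, meiosis had the motif at 0 of 4 and DREAM and synMuv B at 3 of 7. The proteasome list had it at 3 of 4 and the germline RNA-binding list at 7 of 9. Among the other housekeeping lists, proteasome genes were bound at 4 of 24 (16.7%; adjusted exact p = 0.13), at *rpn-11*, *rpn-6.2*, *pas-6* and *rpn-9*, and at 8.33% with replicate 2 alone and 9.09% with replicate 3 alone. Nuclear genes of the respiratory chain list were bound at 2 of 18 (adjusted exact p = 0.54), at *cox-5A* and *cox-5B*. The bound mitochondrial genes ND1 and COX3 were not in this list and counted among the other genes. DNA repair genes were bound at 2 of 28 (7.14%; others 6.11%; adjusted exact p = 1), the checkpoint kinase gene *chk-1* and the Fanconi anaemia gene *fcd-2*. Their share was 11.1% with replicate 3 alone (others 5.02%) and 5% with replicate 2 alone (others 7.01%). The *chk-1* peak ranked 6023 in replicate 2 and 159 in replicate 3. Histone genes were bound at 0 of 16 (up to 20.6% by the exact interval; adjusted exact p = 0.99).

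None of the somatic lists passed the test in either direction. The tagged LIN-35 was driven by the germline-expressed *pie-1* promoter, and its level in somatic tissue was not measured here. These counts therefore cannot tell whether LIN-35 binds such genes in somatic tissue. Neuron genes were bound at 0 of 47 (up to 7.55%; others 6.15%; adjusted exact p = 0.23), vitellogenin and intestine genes at 0 of 5 (up to 52.2%; others 6.12%), muscle genes at 1 of 19 (5.26%, *act-2*; others 6.11%) and cuticle collagens at 2 of 45 (4.44%; others 6.12%). Both bound collagen genes shared their promoter with a gene of another list, *col-38* with *rpl-5* and *col-2* with the kinetochore gene *ndc-80*. Only 2 of the major sperm protein genes had a candidate region, and neither was bound. With replicate 3 alone, muscle genes were bound at 1 of 17 (5.88%; others 5.04%) and collagens at 1 of 55 (1.82%; others 5.06%). With replicate 2 alone, the shares were 1 of 10 (10%; others 7%) and 1 of 34 (2.94%; others 7.03%). The muscle share was thus above that of other genes in either library alone, but it rested on 1 bound gene each time. Neither passed the test (adjusted exact p = 0.72 with replicate 3 alone and 0.75 with replicate 2 alone), so no direction can be read from it. No list had significantly fewer bound genes than the rest. At an unadjusted p under 0.05, 6 lists passed, the 5 above and meiosis, each with more bound genes than the rest.

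**Figure D3:**
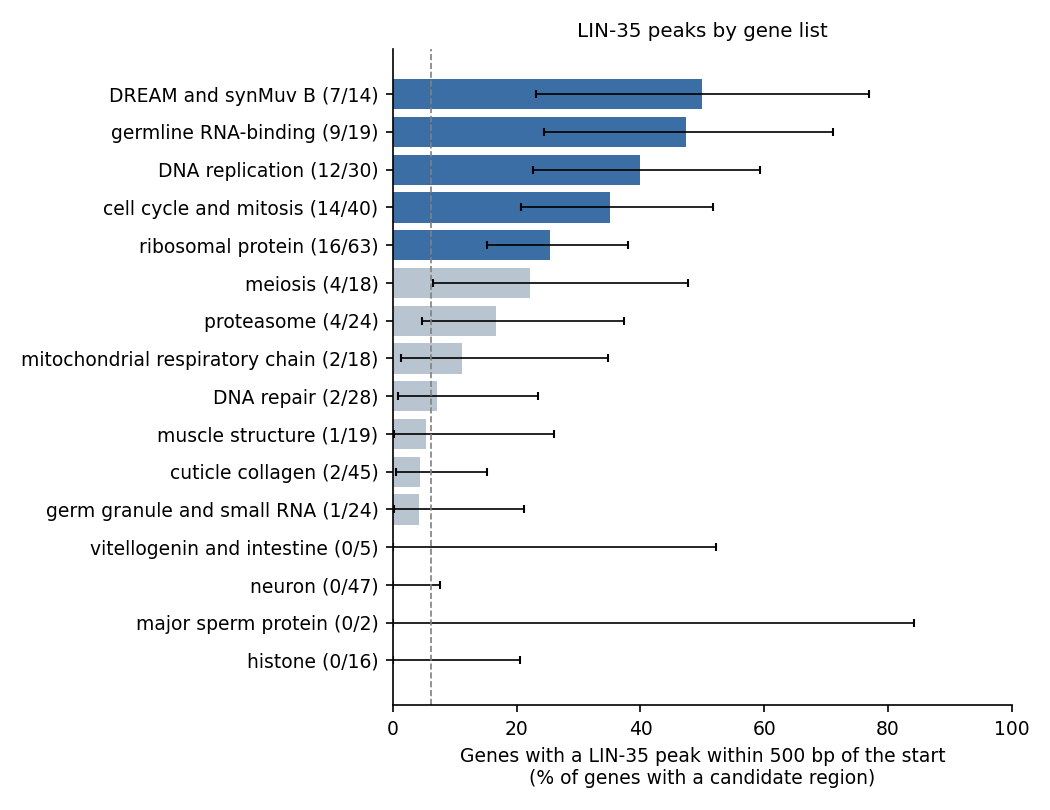
Share of genes in each list with a LIN-35 peak within 500 bp of the start (x axis, percent of the genes with a candidate region), with exact 95% intervals and bound and tested gene numbers in the labels. Dark bars passed an adjusted p of 0.05, and the dashed line is the share over all 6873 genes; the 5 dark bars run from 25.4% to 50%.

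The transgene parts were examined separately, because extra copies of a sequence can add reads at its endogenous position. A control alignment was used in calling, and whether it offsets such reads was not examined here. The *unc-119* gene, expressed in neurons, held 4 thresholded peaks inside its body on chromosome III, between 10904428 and 10908182. Of these peaks, 2 lay in introns and 2, which overlapped each other, in coding exons, so they formed 3 separate loci. In replicate 3 the locus held 4 of the 396 highest-ranked regions, with a best rank of 26, whereas in replicate 2 it held 0, with a best rank of 548. The region around *pie-1* held 3 peaks, with summits 136 bp upstream of the *pie-1* start (rank 121), 276 bp upstream of the neighbouring gene *snr-6* (rank 120) and in a coding exon of *pie-1* (rank 287). At *lin-35* there was 1 peak, 147 bp upstream of the start, with rank 219 in the pooled list, 234 in replicate 2 and 281 in replicate 3.

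**Figure D4:**
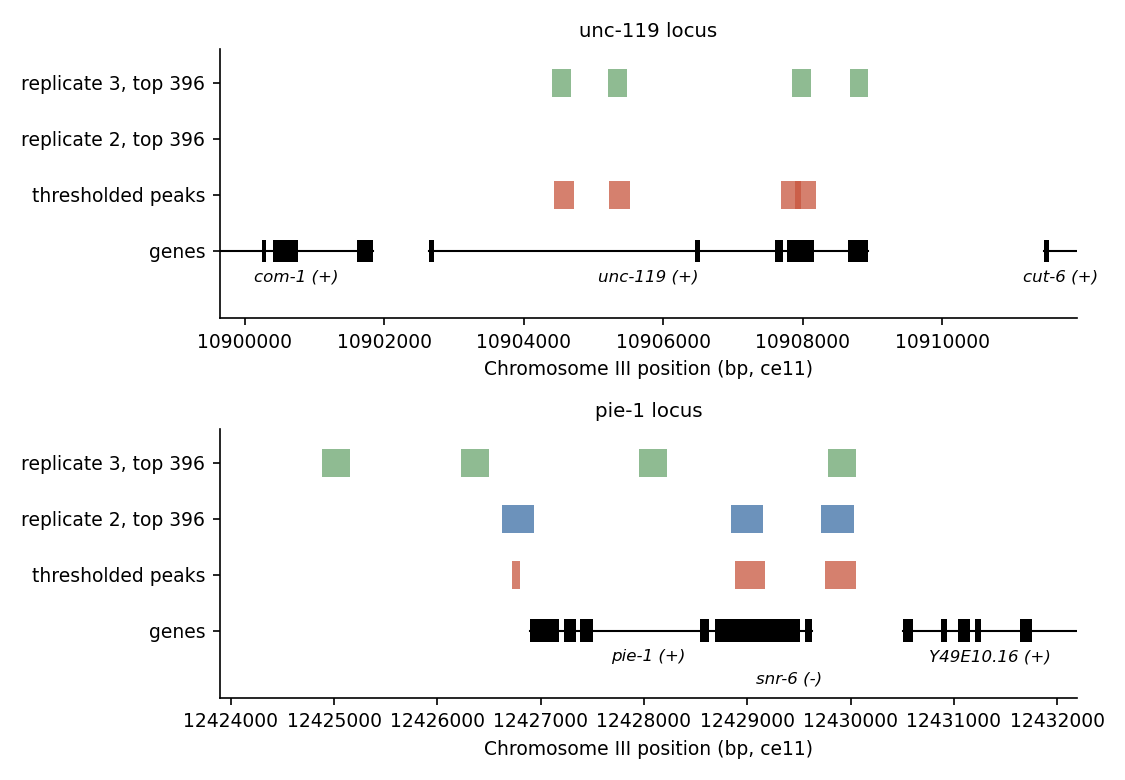
Maps of the *unc-119* and *pie-1* genes with 3000 bp on each side on chromosome III (x axis, position in bp, ce11), with exons as black boxes, thresholded peaks in red and the regions among the 396 highest-ranked of replicate 2 in blue and of replicate 3 in green. At *unc-119*, 4 regions of replicate 3 and 0 of replicate 2 are drawn.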

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

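The alternatives for nuclear peaks only, looser peak lists, peaks outside the transgene parts, GC-matched background and starts of other genes were chosen after seeing the data. The promoter, X chromosome, E2F and CHR shares and the replicate overlap kept their direction and their side of the threshold under each alternative run. The number of bound genes moved from 420 to 207 with the stricter 198 peaks, to 767 with the 1000 highest-ranked pooled regions and to 1129 with the 2000, as fewer or more peaks were used. With a single replicate's 396 highest-ranked regions, the promoter share was 71.0% to 73.2%, the X share 3.03% to 5.30%, the E2F share 38.6% to 44.2%, the CHR share 64.9% to 66.9% and bound genes 338 to 358, with 5 lists enriched each time. The X share was 0 of 198 in the stricter set (up to 1.85%) and 13.4% with 2000 regions. With 2000 regions the promoter share was 46.6% and the E2F share 21.8%, the lowest of all alternatives with the TTSSCGC motif; the cause was not tested. Replicate overlap was 29.1% for the 1000 highest-ranked regions, 41.2% to 45.7% under the other definitions and for nuclear regions, and 46.8% for the ce10 lists. In each alternative 5 to 7 of the 16 lists passed with more bound genes than the rest, and the 5 enriched lists each passed in 12 of 12. With a single replicate, the bound shares of these 5 lists were 26.7% to 41.7% (DNA replication), 21.6% to 39.4% (cell cycle and mitosis), 31.6% to 40.9% (germline RNA-binding), 35.7% to 50% (DREAM and synMuv B) and 24% to 25.4% (ribosomal protein). Germ granule and small RNA genes, bound below the share of other genes at 1 of 24, were above it in 7 of 12 alternatives, among them a single replicate (6.67% and 15%), 1000 regions (6 of 24, others 11.1%) and 2000 (8 of 24, others 16.4%), without passing the adjusted test. Among the other lists, 8 tests crossed the threshold without a change of direction: meiosis in 4 alternatives, proteasome in 2, both with more bound genes than the rest, and neuron in 2, with fewer. No paired analysis was possible because there is a single group. Depth is unknown, so it cannot be told which weaker peaks were missed in either library.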

Other observations

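Apart from the counts with a distance of 1000 bp, the tests in this part were chosen after the peaks had been seen. Among the strongest peaks were genes of the eggshell and oocyte surface, a group not among the lists fixed beforehand. Peaks lay at *cpg-2* (signal 101.1) and *cpg-1* (85.3), encoding chondroitin proteoglycans of the eggshell, *egg-4* (86.0), a pseudophosphatase of egg activation, *rme-2* (81.4), the oocyte yolk receptor, and *chs-1* (77.0), the eggshell chitin synthase. A list of 17 such genes, drawn up from background knowledge once these 5 had been noticed, had 14 members with a candidate region, of which 10 were bound. Apart from the 5 genes that prompted it, the bound members were *cbd-1*, *egg-1*, *egg-3*, *egg-5* and *perm-1*. These counts are descriptive, because the peaks had been seen when the list was drawn up, and a test on it decides nothing. An E2F motif was present at 9 of the 10 peaks.

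Several strong peaks near cell cycle genes fell outside the 500 bp distance. The peak nearest *hcp-3*, encoding the centromeric histone CENP-A, had a signal of 100.4 and lay 671 bp upstream of the annotated start. The peak nearest *hcp-4* (CENP-C) had 70.3 and lay 697 bp upstream, and that nearest *rod-1* had 55.1 and lay 558 bp upstream. All 3 summits carried an E2F motif. With a distance of 1000 bp, 20 of 45 cell cycle and mitosis genes were bound (44.4%). The peak nearest *klp-7*, a microtubule-depolymerising kinesin, had 86.0 and lay in an intron, 1534 bp past the start, without the motif.

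A scan of 2080 6-mers within 75 bp of the summits of promoter peaks found 261 that were more frequent than in both backgrounds (promoter candidate regions and the starts of other genes; adjusted exact p under 0.05), and 150 in the peaks without the E2F motif. The 6-mer with the lowest p, GCGCGA, was present in 109 of 316 nuclear promoter peaks (34.5%) and in 3.18% of 6602 promoter candidate regions (Fisher's exact, adjusted p = 1.5e-67). In the 144 promoter peaks without the E2F motif, CGCGCA was present in 43 (29.9%, against 4.27%; adjusted exact p = 4.1e-20) and ACCGTA in 36 (25%, against 5.60%; adjusted exact p = 1.9e-11). GCGCAA was present in 42 of them (29.2%, against 4.62%; adjusted exact p = 2.6e-18). Its reverse complement, TTGCGC, is TTSSCGC with a single S, so peaks counted as lacking the motif can hold a closely related sequence. ACCGTA was present in 6 of 16 ribosomal protein peaks and in 7 of 25 replication and cell cycle peaks (Fisher's exact p = 0.73). For CGCGCA these counts were 1 of 16 and 10 of 25 (exact p = 0.028) and for GCGCGA 2 of 16 and 12 of 25 (exact p = 0.041), without adjustment for the 3 tests.

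Ribosomal protein genes were bound often, and 12 of their 16 peaks had no E2F motif. A promoter shared with a neighbouring protein-coding gene was argued against as the whole cause. Of 40 ribosomal protein genes, 6 (15%) were bound by a peak with no other protein-coding start within 500 bp (others 3.94%; Fisher's exact p = 0.0048). Starts of non-coding genes were not counted in this test. Without peaks near tRNA, rRNA, snoRNA and snRNA genes, 14 of 63 ribosomal protein genes were bound (22.2%; others 5.68%). The other 10 peaks had another protein-coding start within 500 bp (62.5%, compared with 28.0% of other nuclear promoter peaks; Fisher's exact p = 0.0084) and cannot be assigned to 1 gene. Peaks of other lists were also shared, among them those at *top-2*, *rfc-4*, *csc-1* and *klp-18*. A summit near several starts has more chances to count for a list, so this comparison shows no trait particular to ribosomal protein genes. Nonspecific precipitation at genes transcribed at high levels in any tissue stays open. Collagen, intestine and muscle genes, bound at 3 of 69 (4.35%), had candidate regions less often (30.3% of 228, compared with 80.8% of 78 ribosomal protein genes), and no expression values were used here. A peak of rank 73, with the E2F motif, lay at the tubulin gene *tba-2*. This gene was named after its values were seen, and it decides nothing on this point. Binding at promoters active in the germ line, whatever gene they serve, stays open too, as the 3 germline lists were bound at 14 of 61 (23.0%, against 5.96% of other genes; Fisher's exact p = 1.3e-05) but their expression was not used here, and a difference among them, from 1 of 24 to 9 of 19 (permutation p = 0.0031), missed the threshold in 3 of 12 alternatives, among them replicate 3 alone (permutation p = 0.19) and replicate 2 alone (permutation p = 0.079).

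The 20 mitochondrial peaks stood at the top of the ranking. E2F-directed binding as at nuclear peaks was argued against, since 1 of 20 (5%) had the E2F motif, compared with 196 of 376 nuclear peaks (52.1%; Fisher's exact p = 2.7e-05). The mitochondrial genome has 23.8% GC, and no mitochondrial background was used for the motif. The low share may follow from base composition, so it bears only on binding through this motif. Uneven read depth over the many copies of mitochondrial DNA may account for them, but this stays open. Summits of both replicates lay within 50 bp of each other at 8 of 20 mitochondrial peaks (40.0%) and at 243 of 376 nuclear peaks (64.6%; Fisher's exact p = 0.032), yet the difference missed the threshold among peaks with a region in both libraries (44.4% against 68.1%; p = 0.069). No biological explanation was tested beyond the motif.

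Reads from extra copies of unc-119 in the transgene are a candidate source of the 4 peaks in that gene. With overlapping peaks merged, *unc-119* held 3 loci, and 10 of 19973 nuclear protein-coding genes, itself and *pie-1* included, held as many in the gene and 3000 bp on each side. The transgene is present in both libraries by the labels, yet 4 of the 396 highest-ranked regions lay there in replicate 3 and 0 in replicate 2, so the test leaves this open. E2F-directed binding also stays open, as 0 of the 4 peaks had the motif compared with 196 of 372 other nuclear peaks (52.7%; Fisher's exact p = 0.052), with too few peaks to decide.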
